A study of Alcaligenes ammonioxydans with 12 samples.

How the data were processed

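RNA sequencing was carried out on strain HO-1 of Alcaligenes, a bacterium isolated from a wastewater treatment system. Per the labels' protocols, cells grew aerobically at 30 °C in a medium that held succinate at 83 mM, with ammonium sulfate at 14 mM. After about 58 h the ammonium was used up, ammonium sulfate was given again to 14 mM, and cells were taken 0, 3.5, 10 and 22 h later. The labels describe 3 biological replicates per time, 12 samples in all, and number them 1 to 3 at each time. Cells were spun down and frozen in liquid nitrogen, total RNA was purified with a bacterial RNA kit and treated with DNase I, and paired-end libraries were made with an Illumina TruSeq RNA kit. Whether the libraries keep the strand, and how ribosomal RNA was removed, is not given in the sources used here, so reads from overlapping or antisense genes cannot be separated.

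The authors deposited a table of expected counts per gene, estimates that need not be whole. Bowtie2, RSEM and DESeq2 are named in the submitters' processing notes, without versions. The table held 3747 rows, of which 3374 carried a locus tag and 373 an sRNA number. Of these, 29 rows held a count that was not whole, which can arise where reads are shared between near-identical copies, and 227 rows were at 0 in all libraries, 222 of them sRNA rows. The counts were rounded to whole numbers before testing. The authors also deposited a table of TPM values (transcript abundances corrected for length and scaled to a fixed sum), which gave the strand, start and end of each locus tag on 1 chromosome sequence, with listed genes from position 1 to 3774603. The genome build is not given in the sources used here. All coordinates below are those of that table. There, 7 rows held stray annotation text, and from there on the column of gene lengths was displaced, so that 1597 locus tags had a listed length that differed from their span or was empty. Lengths were therefore taken from start and end. The spans of 3345 locus tags were multiples of 3, so they are coding lengths without untranslated regions. In 152 cases, all in 40 sRNA rows, a count of at least 1 stood beside a TPM of 0, the highest such count being 2244. TPM values were therefore used only in an alternative test.

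The files pair locus tags with no gene names or products, apart from stray text beside 5 of them, and no reference table of names was used here. The 24 gene lists fixed in advance, their enrichment tests (camera and fry), the marker genes chosen by name and the alternative without ribosomal and transfer RNA rows could therefore not be run. The naming rule fixed before the data were examined then allowed at most 2 locus tags or sRNA rows that rose and 2 that fell per comparison. These were the ones with the highest and the lowest log2 fold change among genes that passed the test, had a mean of at least 20 CPM over the 12 samples, and had all 3 replicates of one time above all 3 of the other. The part of that rule that asks for a known product could not be applied. For those 5 the stray text directly after their row names a product, and these names are used as that text gives them.

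Other choices were made after the files had been seen. To describe groups without gene names, runs of neighbouring genes were defined before any run had been computed. A run is at least 4 adjacent genes on 1 strand, with at most 200 bp between neighbours, all past the test and at least 2-fold changed in 1 direction. Runs named in the text are those with the largest mean log2 fold change and a summed mean of at least 100 CPM, up to 3 per direction against 0 h and up to 2 per direction for the later steps, together with the longest run per direction, which was added after the runs had been seen. The number of runs was set against 1000 shuffles of the calls over the tested genes. Shuffling parts neighbours that change together for any reason, such as a shared transcript. An excess over the shuffles thus shows only that calls cluster along the chromosome. The sRNA rows were tested as a class, and the 3 most abundant rows and the third replicates were examined, also after the files had been seen.

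The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, in 1 fit over all 12 libraries with a mean per time and no replicate block. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 3359 genes, 3260 with a locus tag and 99 sRNA rows. Libraries were scaled by TMM (trimmed mean of M values), with factors between 0.703 and 1.38. A gene is said to have passed the test, or to have risen or fallen, where its Benjamini-Hochberg adjusted p was below 0.05. Every adjusted p below comes from this test unless another is named. Levels are CPM, counts scaled to a fixed library size on the TMM scale, given as mean ± SD over 3 replicates. Standard errors (SE) of log2 fold changes come from the residual SD of log2 CPM pooled over the 4 times. That log2 CPM holds a prior count of 2 to steady low values, so the SE is too small where a time has only a few counts. The same holds for the SE of a run in which some genes have only a few counts at a time. The sRNA class was tested with camera from limma 3.58.1, with a preset correlation between genes of 0.01 and again with an estimated one, and with Fisher's exact test on the numbers of rises and falls, each adjusted over the 5 comparisons.

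Total counts ran from 6641845 to 9444649 per library. Intervals of count ratios are exact Clopper-Pearson intervals at 95% and cover counting error only. Replicates were compared before averaging: the lowest chi-square per degree of freedom between 2 libraries of a time was 10.44, so no library appeared to have been deposited again under another number. Whether equal replicate numbers pair the libraries was checked from the correlation of deviations from the group means. From 3.5 to 10 h all 3 pairs with 1 number correlated by over 0.1 (0.16 to 0.29), as did 1 of 6 pairs with different numbers (0.12), so these numbers meet the rule for pairing. The values given below for this step still come from the test without a replicate block, and the block is an alternative. The pairing comes from the data alone, since the labels name no shared culture, batch or day. In the other 4 comparisons not all pairs did. The test was tried on simulated counts for 3.5 h against 0 h with 200 changed genes among 3338 that were tested. Of 50 genes at each size, 54% were called in the true direction at 1.5-fold, 78% at 2-fold, 98% at 4-fold and 100% at 8-fold. Of 170 genes called, 5 were unchanged, or 2.94%. In the real comparison 2448 genes passed, far more than the 200 changed here. The adjusted p then sets a more lenient bound, so these shares do not carry over to it. The simulation did not model a change in the share of the most abundant rows, so it does not test the scaling.

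Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, scaling by total counts, no filter on low counts, a filter of 10 CPM in at least 3 samples, DESeq2 1.42.0, limma on log2(TPM + 1), a replicate block, fits over 2 times only, and leaving out each library in turn. Added later were total counts after leaving out the 3 most abundant rows, leaving out the third library of every time, and runs with at least 3 genes or gaps of at most 50 bp. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.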

Results

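The transcriptome of HO-1 was followed over 22 h after ammonium was given back to a culture that had used it up. Libraries from 0, 3.5, 10 and 22 h were compared, with 3 biological replicates each. Total counts lay between 6893418 and 8341734 at 0 h, between 6641845 and 9216541 at 3.5 h, between 7295795 and 8795910 at 10 h, and between 7348565 and 9444649 at 22 h. The time points separated on the first 2 principal components, which held 56.8% and 29.5% of the variance. Correlations of log2 CPM between replicates, taken across genes, were 0.9807 or higher. Of 3359 genes tested, 3169 (94.3%) differed between at least 2 of the times by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment.

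**Figure D1:**
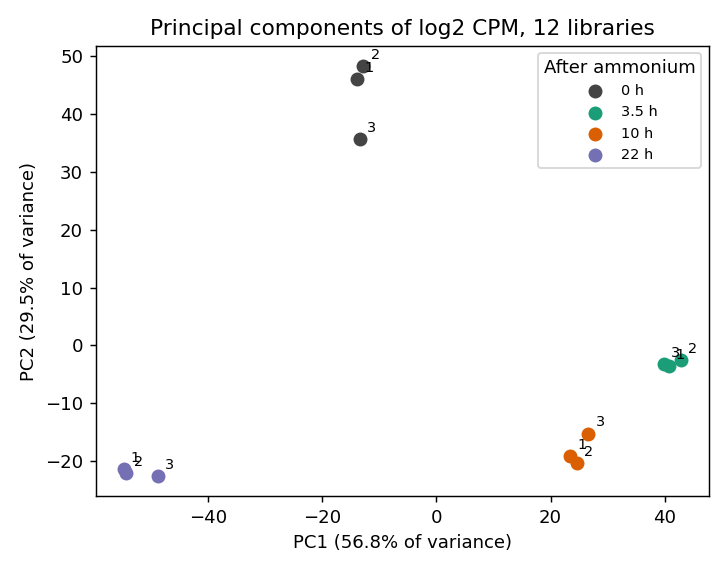
Principal components of log2 CPM for the 12 libraries, coloured by hours after ammonium and marked with the replicate number. The horizontal axis (56.8% of variance) separates 22 h from 3.5 and 10 h, and the vertical axis (29.5%) separates 0 h from the later times.

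The 3 most abundant rows together took 41.57 ± 1.165% of all counts at 0 h, 23.81 ± 1.78% at 3.5 h, 38.38 ± 1.479% at 10 h and 52.61 ± 2.486% at 22 h (SD, n = 3). They lie at 2466362 to 2466723 (minus strand, 362 bp), 796526 to 796932 (plus strand, 407 bp) and 2911213 to 2911396 (minus strand, 184 bp), and were singled out after their values were seen. The first of them alone held 16.22 ± 0.715% of counts at 3.5 h and 33.76 ± 3.19% at 22 h. All 3 fell at 3.5 h against 0 h, by 1.43, 1.39 and 2.03 on the log2 scale, with adjusted p of 5.75e-06, 1.22e-06 and 1.83e-05. All 3 rose from 10 to 22 h, with log2 fold changes of 1.01, 0.94 and 1.27. The choice of scaling shifts every gene. Scaling by total counts in place of TMM moved the median log2 fold change of all genes by 0.69 at 3.5 h, 0.44 at 10 h and -0.12 at 22 h, each against 0 h, by -0.25 from 3.5 to 10 h and by -0.56 from 10 to 22 h. Changes below are relative to the TMM scale.

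**Figure D2:**
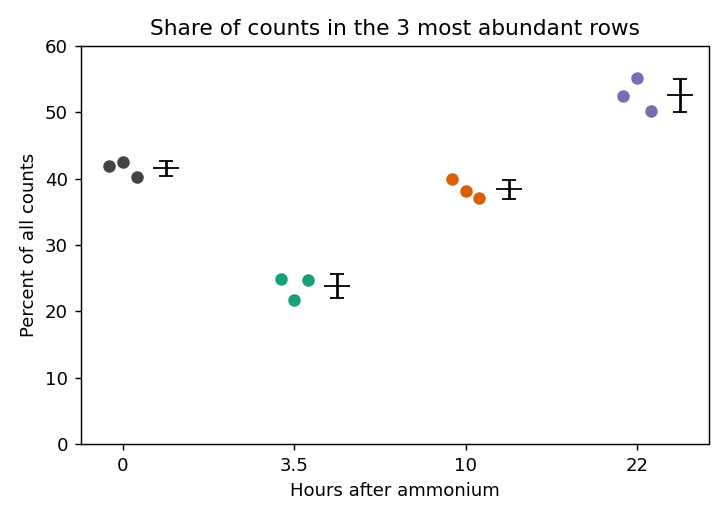
Percent of all counts in the 3 most abundant rows (vertical axis) by hours after ammonium (horizontal axis, times evenly spaced). Coloured points are libraries, and black bars give mean ± SD (n = 3), lowest at 3.5 h (23.81%) and highest at 22 h (52.61%).

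The first comparison asked what changed within 3.5 h of renewed ammonium. Among the runs, the largest mean rise was in 7 adjacent plus-strand genes at 3399639 to 3408499, whose summed level went from 13.7 ± 5.08 to 1550 ± 840 CPM (SD, n = 3; mean log2 fold change 6.58, SE 0.48). A run of 9 minus-strand genes at 2389369 to 2396024 went from 69.8 ± 2.31 to 4530 ± 369 CPM (mean log2 fold change 5.62, SE 0.07). A run of 14 plus-strand genes at 1300248 to 1314243 went from 50.1 ± 5.12 to 669 ± 298 CPM (4.03 on the log2 scale, SE 0.34). The longest run, 19 minus-strand genes at 2015573 to 2039715, went from 76.1 ± 6.37 to 319 ± 25.4 CPM, a mean log2 fold change of 2.19. The 1 run that fell held 6 minus-strand genes at 1990770 to 1993860, which went from 2350 ± 235 to 948 ± 21.7 CPM (-1.28 on the log2 scale, SE 0.1).

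Among single genes, FE795_15615, within the run at 3399639 to 3408499, rose from 1.91 ± 0.468 to 1000 ± 572 CPM (log2 fold change 9.06, SE 0.51, adjusted p = 2.22e-08). FE795_11035, within the run at 2389369 to 2396024, rose from 6.04 ± 0.787 to 1500 ± 115 CPM (7.95, SE 0.12, adjusted p = 9.39e-13). FE795_16205 (3540804 to 3542630, minus strand) fell from 1570 ± 548 to 40.4 ± 4.33 CPM (-5.28, SE 0.21, adjusted p = 5.4e-10). FE795_00750, a 270 bp gene at 175347 to 175616 on the plus strand, fell from 52.4 ± 37.6 to 1.38 ± 0.306 CPM (-5.22, SE 0.75, adjusted p = 1.46e-05). At 0 h its replicates stood at 67.3, 80.3 and 9.57 CPM.

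In all, 2448 genes passed the test at 3.5 h against 0 h, 1273 higher and 1175 lower, and 689 were at least 2-fold higher and 468 at least 2-fold lower. Runs of neighbouring genes numbered 36 higher and 1 lower, against at most 6 and 4 in 1000 shuffles, and the higher runs held 247 genes. The number of lower runs thus lay within the range of the shuffles. Taking runs of at least 3 genes gave 65 and 10 (at most 21 and 9 in shuffles), and gaps of at most 50 bp gave 24 and 0 (at most 5 and 2). With total-count scaling there were 75 higher and 0 lower runs, with log2(TPM + 1) 109 and 0, and DESeq2 or its size factors gave 2 lower runs. Of the genes that passed, 52% were higher, against 83% with total-count scaling and 94.8% with limma on log2(TPM + 1). The run at 1990770 to 1993860 includes 2 genes with non-whole counts, and on log2(TPM + 1) its mean change was -0.07. Without replicate 3 of 0 h the run at 3399639 to 3408499 rose by 7.32, and without the third library of every time by 7.70. A second lower run appeared in both of these settings and without replicate 2 of 3.5 h.

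**Figure D3:**
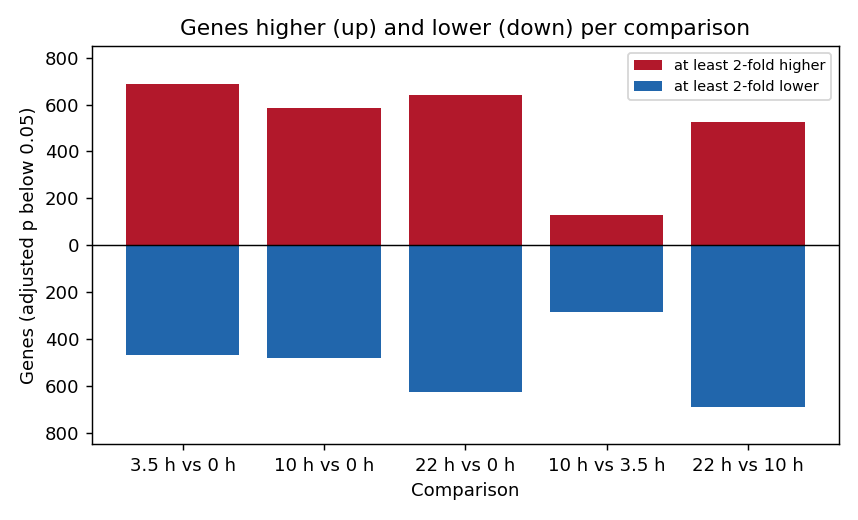
Number of genes (vertical axis) at least 2-fold higher (red, upward bars) or lower (blue, downward bars) with adjusted p below 0.05 in each of the 5 comparisons (horizontal axis). The step from 3.5 to 10 h had the fewest, 129 higher and 285 lower.

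At 10 h against 0 h, the run of 9 genes at 2389369 to 2396024 stood at 8060 ± 192 CPM, a mean log2 fold change of 6.33 (SE 0.07). A run of 9 minus-strand genes at 2805583 to 2819068 went from 501 ± 49.5 to 8310 ± 267 CPM (4.62, SE 0.16), and the 14 genes at 1300248 to 1314243 stood at 734 ± 195 CPM (4.06, SE 0.34). The lower runs included 4 minus-strand genes at 3714129 to 3718498 that went from 17500 ± 4730 to 2600 ± 156 CPM (-2.68, SE 0.22). Of these 4 genes, 1 has non-whole counts. Runs of 4 genes each at 1181793 to 1183358 (plus strand) and at 3772023 to 3774603 (minus strand) went from 2390 ± 470 to 397 ± 44 CPM and from 1460 ± 321 to 271 ± 10.2 CPM. The longest lower run, 10 minus-strand genes at 3646647 to 3650720, went from 4840 ± 1030 to 950 ± 29.7 CPM, a mean log2 fold change of -2.12.

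FE795_11035 rose to 2940 ± 84.4 CPM by 10 h (log2 fold change 8.93, SE 0.12, adjusted p = 3.25e-13). FE795_11025, a 174 bp gene at 2392363 to 2392536 in the same run, rose from 0.284 ± 0.23 to 113 ± 22.5 CPM (8.65, SE 0.37, adjusted p = 1.22e-10), with counts of 1, 3 and 1 at 0 h. At such counts this SE is too small, and without replicate 2 of 0 h the change of FE795_11025 was 9.42. FE795_15520 (3376302 to 3377294, minus strand) fell from 194 ± 34.5 to 8.52 ± 2.54 CPM (-4.50, SE 0.23, adjusted p = 1.24e-09). FE795_16205 stood at 73.4 ± 1.99 CPM, a change of -4.42 (SE 0.21, adjusted p = 1.46e-09).

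At this time 2412 genes passed the test, 1274 higher and 1138 lower, with 586 at least 2-fold higher and 482 at least 2-fold lower. Runs numbered 25 higher and 10 lower, against at most 5 and 3 in 1000 shuffles. Taking at least 3 genes they were 49 and 27 (at most 13 and 11 in shuffles), and with gaps of at most 50 bp 18 and 4 (at most 3 and 2). Scaling by total counts made them 52 and 5, or 46 and 6 after leaving out the 3 most abundant rows, and log2(TPM + 1) 46 and 5. Of the 689 genes at least 2-fold higher at 3.5 h, 452 were so at 10 h, where independent lists would share 120. Of the 468 that were at least 2-fold lower, 287 were so at 10 h, where independent lists would share 67.2. Both comparisons use the same 0 h libraries, too few to split. In 10 simulations of unchanged groups the overlap between any 2 comparisons with 0 h was 0. Unchanged groups gave no lists to overlap, so this value says nothing about lists of this length. Part of the excess may come from the shared controls. The 2 overlaps were 914 and 96 with total-count scaling, 722 and 164 with total counts after leaving out the 3 most abundant rows, and 986 and 40 on log2(TPM + 1). These scalings change the lengths of the lists as well, so 120 and 67.2 are not the values to set beside them. Of the genes that passed, 52.8% were higher, against 73.7% with total-count scaling, 82.7% on log2(TPM + 1), and 70.1% with total counts after leaving out the 3 most abundant rows.

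At 22 h another set of runs led the list of rises. A run of 5 plus-strand genes at 71522 to 76746 went from 21.4 ± 0.288 CPM at 0 h to 3370 ± 2160 CPM (mean log2 fold change 7.40, SE 0.61), and was at 25.3 ± 2.18 CPM at 3.5 h. A run of 4 plus-strand genes at 496200 to 501831 went from 261 ± 27.3 to 2900 ± 825 CPM (3.24, SE 0.15), and 6 plus-strand genes at 51311 to 58042 went from 129 ± 4.24 to 641 ± 251 CPM (2.56, SE 0.34). The 5 minus-strand genes at 3713671 to 3718498 fell from 17900 ± 4810 to 1460 ± 168 CPM (-3.41, SE 0.22). Of these 5 genes, 1 has non-whole counts. A run of 4 minus-strand genes at 1684309 to 1688774 fell from 1070 ± 107 to 121 ± 4.1 CPM (-3.30, SE 0.1), and the 4 genes at 1181793 to 1183358 were down to 252 ± 26.9 CPM (-3.36, SE 0.17).

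The longest lower run at 22 h held 17 minus-strand genes at 3642349 to 3650720, from 6170 ± 1280 CPM at 0 h to 1060 ± 206 CPM (-2.35 on the log2 scale). The longest higher run, 7 plus-strand genes at 187812 to 193855, went from 52.1 ± 10.5 to 329 ± 25.2 CPM (2.40). FE795_00310 and FE795_00325, both in the run at 71522 to 76746, rose by log2 fold changes of 7.76 (SE 0.7, adjusted p = 3.1e-07) and 7.71 (SE 0.63, adjusted p = 2.33e-07). FE795_00310 reached 823, 947 and 141 CPM in replicates 1, 2 and 3. FE795_14080 (3064845 to 3066236, plus strand) fell from 3620 ± 956 to 26.3 ± 1.27 CPM (-7.10, SE 0.2, adjusted p = 2.23e-10), and FE795_07940 (1739552 to 1740574, plus strand) from 251 ± 89.7 to 7.45 ± 1.69 CPM (-5.07, SE 0.28, adjusted p = 3.68e-09).

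At 22 h against 0 h 2487 genes passed the test, 1295 higher and 1192 lower, and 640 were at least 2-fold higher and 628 at least 2-fold lower. Runs numbered 25 higher and 32 lower, against at most 5 in either direction in 1000 shuffles. At least 3 genes gave 49 and 64 (at most 15 and 18 in shuffles), and gaps of at most 50 bp 11 and 18 (at most 3 in either direction). The higher runs became 16 with a filter of 10 CPM and 10 on log2(TPM + 1). Of the 689 genes at least 2-fold higher at 3.5 h, 155 were also at least 2-fold higher at 22 h and 73 at least 2-fold lower, where independent lists would share 131 and 129. Of the 468 genes at least 2-fold lower at 3.5 h, 149 were so at 22 h as well and 83 were at least 2-fold higher, where independent lists would share 87.5 and 89.2. With total-count scaling, which changes the lists too, these overlaps were 250, 211, 56 and 26. Total counts after leaving out the 3 most abundant rows made the first 290 and the third 89. On log2(TPM + 1) the second became 341 and the last 2 became 21 and 8. The 0 h libraries are shared here too. Of the genes that passed, 52.1% were higher, against 32.8% on log2(TPM + 1).

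**Figure D4:**
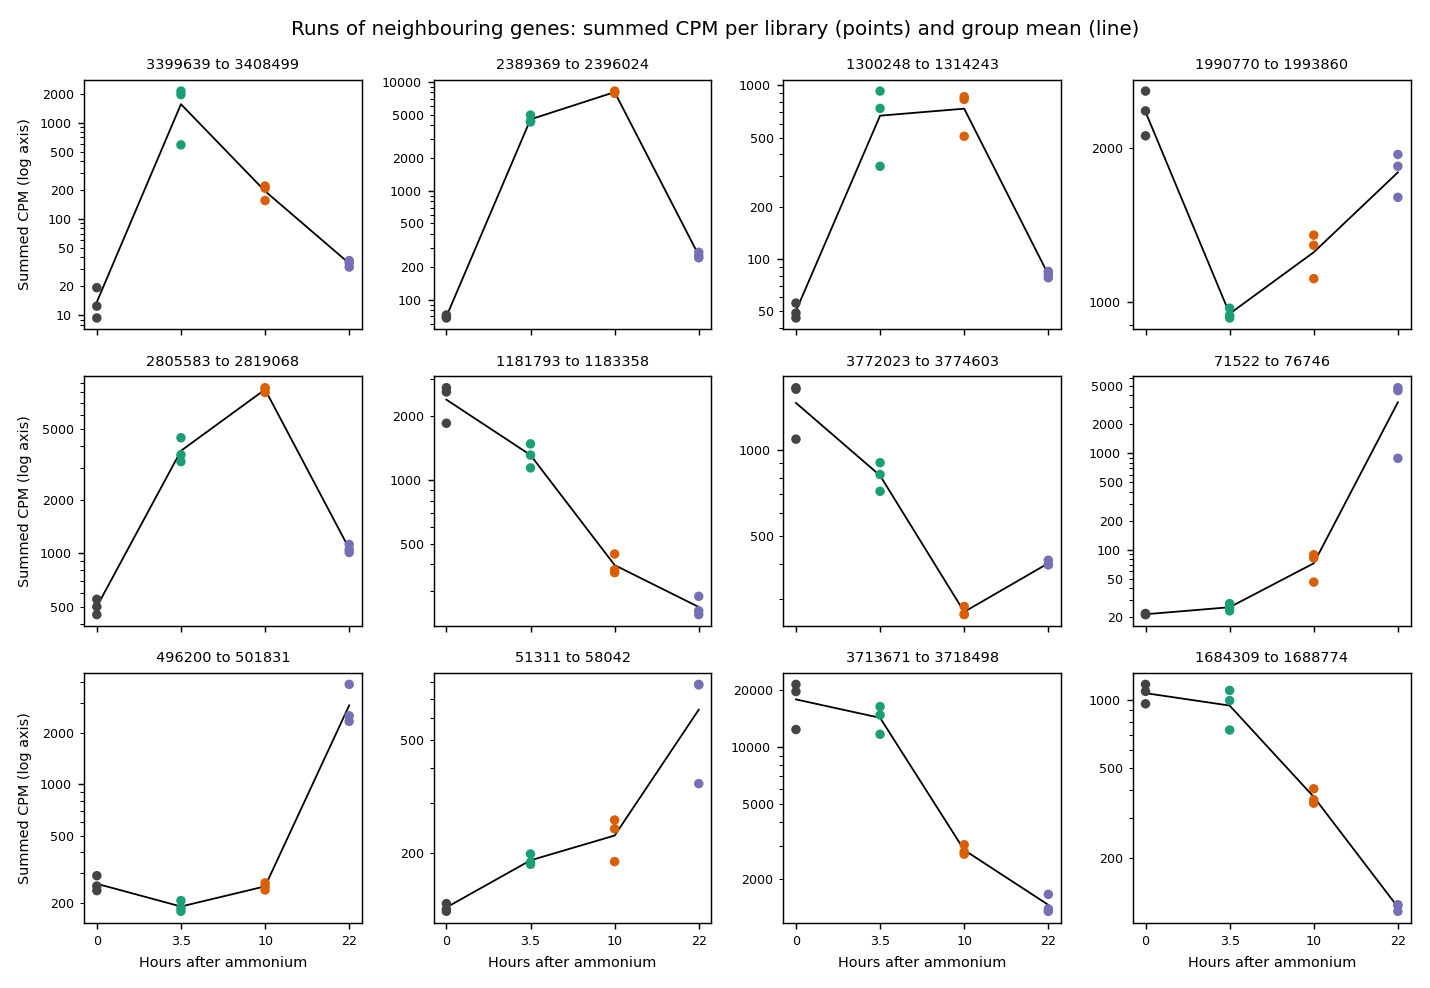
Summed CPM (vertical log axes, 1 scale per panel) of 12 runs of neighbouring genes named for the comparisons with 0 h, titled by start and end position, against hours after ammonium (evenly spaced). Points are libraries and lines join group means. The run at 2389369 to 2396024 peaks at 10 h (8060 CPM), and the run at 71522 to 76746 is high at 22 h, at 4450, 4770 and 885 CPM in replicates 1, 2 and 3.

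From 3.5 to 10 h fewer genes changed. The run at 3399639 to 3408499 fell from 1550 ± 840 to 194 ± 34.2 CPM (mean log2 fold change -2.79, SE 0.48), and 10 minus-strand genes at 3705663 to 3710384 fell from 13600 ± 2970 to 1880 ± 104 CPM (-2.79, SE 0.23). The longest run, the 17 genes at 3642349 to 3650720, fell from 7930 ± 1620 to 1930 ± 64.8 CPM (-2.01). In the other direction, 5 minus-strand genes at 282570 to 286983 rose from 1400 ± 109 to 3530 ± 97.6 CPM (1.37, SE 0.13), and 5 minus-strand genes at 2408903 to 2412640 from 151 ± 68.2 to 478 ± 135 CPM (1.67, SE 0.58).

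Between these times FE795_06625 (1463905 to 1465128, plus strand) rose from 17.2 ± 3.16 to 190 ± 36.6 CPM (3.47, SE 0.59, adjusted p = 0.000196). FE795_14400 (3139853 to 3143320, plus strand) rose from 38.5 ± 8.35 to 340 ± 42.2 CPM (3.15, SE 0.36, adjusted p = 5.25e-06). The row sRNA0315, for which the files give no position used here, fell from 106 ± 88.2 to 4.65 ± 2.03 CPM (-4.51, SE 1.18, adjusted p = 0.00079), and its change was -3.84 without replicate 2 of 3.5 h. FE795_14735 (3208307 to 3210589, minus strand) fell from 1270 ± 990 to 84.4 ± 27.6 CPM (-3.92, SE 0.88, adjusted p = 0.000305). Its 3.5 h replicates stood at 1650, 2020 and 152 CPM.

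The step took in 1707 genes past the test, 841 higher and 866 lower, with 129 at least 2-fold higher and 285 at least 2-fold lower. Runs numbered 4 higher and 17 lower, against at most 1 in either direction in 1000 shuffles, and the 4 became 2 without replicate 2 of 3.5 h or replicate 1 of 10 h. At least 3 genes gave 8 and 29 (at most 1 and 5 in shuffles), and gaps of at most 50 bp 3 and 8 (at most 0 and 1). Total-count scaling gave 0 higher and 28 lower runs, and log2(TPM + 1) 0 and 38. Of the genes that passed, 49.3% were higher, against 21.4% with total-count scaling and 4.97% on log2(TPM + 1). The run at 2408903 to 2412640 rose by 2.28 when the third library of every time was left out.

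From 10 to 22 h the early runs came down. The 7 minus-strand genes at 2389912 to 2396024 fell from 7860 ± 175 to 142 ± 15.6 CPM (mean log2 fold change -6.52, SE 0.07), and the 5 genes at 282570 to 286983 fell from 3530 ± 97.6 to 254 ± 22.7 CPM (-4.44, SE 0.13). The SE of the first run is too small, since FE795_11025 and FE795_11040 within it had few counts at 22 h. Its mean change was -6.82 without replicate 1 of 22 h. The longest run, the 14 genes at 1300248 to 1314243, fell from 734 ± 195 to 81.3 ± 3.43 CPM (-3.90). Meanwhile the 5 genes at 71522 to 76746 rose from 72.2 ± 22.8 to 3370 ± 2160 CPM (5.74, SE 0.61), and 4 minus-strand genes at 2996426 to 3001339, of which 3 have non-whole counts, from 65.6 ± 11.6 to 687 ± 74.7 CPM (3.08, SE 0.13). A run of 6 plus-strand genes at 230578 to 237653, the longest that rose, went from 46.9 ± 7.06 to 209 ± 9.14 CPM (2.10).

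FE795_00310 rose from 4.98 ± 1.8 to 637 ± 434 CPM (6.99, SE 0.7, adjusted p = 3.81e-07), and FE795_00750 from 2.75 ± 1.18 to 281 ± 34.6 CPM (6.66, SE 0.75, adjusted p = 6.18e-07). FE795_11040, a 186 bp gene at 2394869 to 2395054 in the run at 2389912 to 2396024, had 1120 counts at 10 h and 2 at 22 h, a scaled ratio of 391 (95% counting interval 108 to 3230). Its fitted log2 fold change of -8.41 (SE 0.31, adjusted p = 2.13e-10) depends on single counts and became -11.42, -7.78 and -7.79 without replicate 1, 2 or 3 of 22 h. At so few counts this SE is too small. FE795_11025 fell by 7.99 on the log2 scale (SE 0.37, adjusted p = 9.86e-11), and had a change of -8.67 without replicate 2 of 22 h.

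Over this step 2423 genes passed the test, 1130 higher and 1293 lower, with 525 at least 2-fold higher and 690 at least 2-fold lower. Runs numbered 11 higher and 36 lower, against at most 4 and 6 in 1000 shuffles. With at least 3 genes they were 33 and 63 (at most 11 and 21 in shuffles), and with gaps of at most 50 bp 5 and 26 (at most 2 and 5). Total-count scaling gave 3 and 72, log2(TPM + 1) gave 2 and 98, and a filter of 10 CPM left 5 higher runs. Of the genes that passed, 46.6% were higher, against 21.6% with total-count scaling and 11% on log2(TPM + 1).

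The 99 sRNA rows that could be tested were compared with the locus tags as a class. At 3.5 h against 0 h, 21 rose, 53 fell and 25 did not pass, with a median log2 fold change of -0.65. The locus tags had a median of 0.08. The sRNA median was 0.032 with total-count scaling and 0.77 on log2(TPM + 1), so its sign rests on the scaling. The median of all tested genes was then 0.75 and 1.06, so the sRNA median stayed below it. At 10 h against 0 h 28 rose and 26 fell. At 22 h 50 rose and 17 fell, with a median of 0.58. From 3.5 to 10 h 47 rose and 12 fell (median 0.67, but -0.032 on log2(TPM + 1)), and from 10 to 22 h 53 rose and 21 fell (median 0.60, but -0.278 on log2(TPM + 1)). For all genes the medians of these steps on log2(TPM + 1) were -0.45 and -0.91, so the sRNA medians lay above them. A TPM of 0 stood beside a count in 3 of the 99 rows. Without them the sRNA medians on log2(TPM + 1) were 0.78 at 3.5 h against 0 h, and -0.041 and -0.37 in the later steps. By camera with a preset correlation the adjusted p was 0.0103 at 3.5 h, 0.925 at 10 h and 0.0108 at 22 h, each against 0 h, and 9.95e-05 and 0.00698 for the later steps. With an estimated correlation none of these passed: adjusted p = 0.107, 0.946, 0.107, 0.064 and 0.107. Fisher's exact test of rises and falls against those of the locus tags gave adjusted p of 7.33e-05, 0.891, 0.000206, 8.75e-06 and 3.55e-05. That test treats genes as independent and ignores the correlation between them, estimated at 0.0263, so its p-values are likely too small. The numbers of rises and falls also rest on the TMM scale.

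Product names stand beside 5 locus tags, all between 1963230 and 1983062, and this region was singled out after the files had been seen. Of its 20 genes 19 could be tested. At 3.5 h against 0 h 10 of them rose and 4 fell, at 10 h 13 rose and 2 fell, and at 22 h 11 rose and 4 fell. FE795_09060 and FE795_09085, both named as Tn3 family transposases (enzymes that move transposons), rose at 3.5 h. The first went from 11.1 ± 0.47 to 69.3 ± 5.53 CPM (log2 fold change 2.64, SE 0.15, adjusted p = 1.21e-08), and the second from 27 ± 3.35 to 110 ± 16.8 CPM (2.02, SE 0.15, adjusted p = 5.2e-08). FE795_09140, named as the chloramphenicol acetyltransferase CatB3, a resistance enzyme, was higher at 3.5 h (0.24, SE 0.06, adjusted p = 0.0206) and at 10 h (0.25, adjusted p = 0.0173). At 22 h it was lower, at 424 ± 27.6 against 874 ± 24.3 CPM (-1.04, adjusted p = 1.71e-07). With DESeq2 size factors the 2 rises of FE795_09140 did not pass (adjusted p = 0.112 and 0.0815), and with DESeq2 that at 3.5 h did not (0.0581). Both failed to pass without replicate 1 of 0 h (0.0775 and 0.0666), that at 3.5 h also without replicate 1 or 2 of 3.5 h (0.0555 and 0.0621), and that at 10 h without replicate 2 of 10 h (0.0784). FE795_09155, named as the integrase IntI1 of class 1 integrons, was higher at 22 h, at 25.5 ± 2.69 against 12.3 ± 4.52 CPM (1.02, SE 0.24, adjusted p = 0.000635). FE795_09090, named as a resolvase, had log2 fold changes of 0.22 (adjusted p = 0.155) at 3.5 h, 0.79 (adjusted p = 0.000164) at 10 h and 0.57 (adjusted p = 0.00196, but 0.459 on log2(TPM + 1)) at 22 h. In this region 3 genes have non-whole counts, none of them among the 5 named.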

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

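The tests of the third replicates' timing and of their counting noise at 20 CPM or more were chosen only after the results were seen. Among the genes named for the comparisons, those with opposite changes at 3.5 and 22 h, each against 0 h, were picked out where the direct difference between 22 and 3.5 h also passed edgeR's test. Genes not named were not examined in this way. FE795_00750 fell at 3.5 h (-5.22) and rose at 22 h (2.44), with a log2 fold change of 7.66 between them (adjusted p = 1.92e-07). FE795_14400 was lower at 3.5 h (-1.12) and higher at 22 h (6.42), with a log2 fold change of 7.54 (adjusted p = 9.72e-10) and levels of 8480, 8560 and 4410 CPM at 22 h. FE795_11040 was higher at 3.5 h (5.25) and lower at 22 h (-3.39), with a fitted log2 fold change of -8.63 (adjusted p = 9.33e-11). The last value rests on 2 counts at 22 h: the scaled ratio of 3.5 to 22 h was 457 (95% counting interval 126 to 3770), that of 0 to 22 h was 11.8 (2.94 to 103), and the fitted value was -11.67, -8.03 and -8.04 without replicate 1, 2 or 3 of 22 h.

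The 3 most abundant rows (362, 407 and 184 bp) took more of the counts at 22 h than at 3.5 h, which raises the question whether libraries kept short RNA to different degrees. Other genes of 150 to 450 bp (480 genes) did move up from 3.5 to 22 h against longer ones, by a median of 0.45 on the log2 scale (95% bootstrap interval 0.31 to 0.67). The bound of 0.99 set beforehand, 0.5 of the rows' median rise of 1.98, was wrong for this purpose. Spans of 479 of the 480 genes are multiples of 3 and so coding lengths, not transcript lengths, and none of the 3 rows has such a span. A length bias thus cannot be told apart from a change in the cells with time.

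The third replicate stood apart from the other 2: in genes of at least 20 CPM it lay over 2-fold from their mean in 126 cases over the 4 times, whereas replicates 1 and 2 differed from each other by over 2-fold in 16. In 100 simulated libraries with counting noise only, the highest numbers of such cases at the 4 times summed to 8. That argues against counting noise alone for the 126 cases in genes of at least 20 CPM. A spread between single cultures may hold more than counting noise, so the simulation could not decide what else set these cases apart. Over all tested genes, 26.8% of such cases lay above the median expression, so most were in low genes, where noise is a candidate explanation. Sampling at another point of the time course was examined by correlating, across genes, the third replicate's deviation with the change to the adjacent time, in a form revised after a first version shared libraries between both sides: r was 0.24 at 0 h, 0.43 at 3.5 h, -0.14 at 10 h and 0.23 at 22 h. The lowest size, 0.14, lies between both bounds set for the test, so a shift in timing cannot be told apart from other differences between cultures.

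For each comparison of 3 against 3 libraries there are 10 splits, so no share below 0.1 can be reached. The real split gave 2448, 2412 and 2487 genes at 3.5, 10 and 22 h against 0 h, 1707 from 3.5 to 10 h and 2423 from 10 to 22 h, and the highest other split gave 0 in each. From 3.5 to 10 h, where the numbers pair the libraries, 3 of the other splits part all 3 pairs as the real one does, and the remaining 6 part 1 pair and keep 2 together. For the test over all 4 times, 1 of 100 drawn splits, the real one, gave 3169 genes and the highest other gave 1061. Random groupings thus seldom gave as many. No share below 1 of 100 can be reached with these draws, so chance is unlikely there but not excluded.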

How the results depend on the processing

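The settings with total counts after leaving out the 3 most abundant rows and without the third library of every time were chosen after the data were seen, as were all settings for runs, overlaps and the sRNA class, and the test of scaling at 10 h against 0 h. Of the comparisons of gene counts with their alternatives, 535 stayed within 1.5 times and 36 did not, all of them under scaling by total counts (with or without those 3 rows) or limma on log2(TPM + 1). Most alternatives kept TMM scaling, so most of the 535 do not test the scaling. The 36 show that the split into higher and lower genes depends on it. With total counts only, at 3.5 h against 0 h 2093 genes were higher and 429 lower, 1359 and 140 of them by 2-fold or more. At 10 h against 0 h 646 were lower, and 1042 and 258 were at least 2-fold higher and lower. From 3.5 to 10 h 325 were higher, and 60 and 443 at least 2-fold higher and lower. From 10 to 22 h 538 were higher and 1955 lower, 283 and 1206 by 2-fold or more. On log2(TPM + 1), the numbers higher and lower were 2638 and 146 at 3.5 h (1752 and 51 by 2-fold) and 1982 and 415 at 10 h (1053 and 180), while at 22 h 667 were higher (299 by 2-fold). For the later steps they were 86 and 1645 (17 and 624 by 2-fold), and 296 and 2393 (164 and 1545). After leaving out the 3 rows, 274 genes were at least 2-fold lower at 3.5 h, and at 10 h 746 were lower, 296 by 2-fold, and 960 at least 2-fold higher. The median of the sRNA rows turned to 0.032 with total counts and 0.77 on log2(TPM + 1) at 3.5 h against 0 h, and on log2(TPM + 1) to -0.032 from 3.5 to 10 h and -0.278 from 10 to 22 h. These settings moved all genes, whose medians were 0.75, 1.06, -0.45 and -0.91 in the same order. The sRNA median thus stayed below that of all genes at 3.5 h and above it in the later steps. No named gene or run reversed under any setting run, and no gene named by rank lost its call in the comparison it is named for. Of the 5 genes with product names, FE795_09140 at 3.5 and 10 h and FE795_09085 and FE795_09090 at 22 h, each against 0 h, lost a call under some setting. Leaving out the 3 rows brought the median log2 fold change under total counts 68.8% of the way back to its TMM value from 10 to 22 h, so those rows may account for most of that shift. At 10 h against 0 h it brought back only 17.6%, so there they do not account for most of it. At 22 h against 0 h the median moved further from its TMM value, with a shift of 0.18 in place of -0.12. The shift went from 0.69 to 0.30 at 3.5 h against 0 h, and from -0.25 to 0.06 from 3.5 to 10 h.

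The replicate numbers met the rule for pairing for the libraries of 3.5 and 10 h only. There the replicate block gave 1781 genes and changed no call of a named gene or of the sRNA class. Of all 18 pairs with 1 number, 5 correlated by over 0.1 (range -0.03 to 0.29). Elsewhere the rule was not met, but a weaker pairing is not excluded. Between 0 and 3.5 h, 2 of 3 pairs with 1 number correlated by over 0.1, and 0 of 6 other pairs did. In the remaining 3 comparisons 0 of 3 pairs with 1 number did. Even so, 11 of 12 libraries correlated best with their own number. With the block the numbers of genes were 2491, 2446 and 2506 against 0 h, 2443 from 10 to 22 h and 3174 over all times. The alternative without ribosomal and transfer RNA rows and all gene list tests were not run. In simulated counts for 3.5 h against 0 h a 1.5-fold change was recovered in 54% of genes, so small changes can be missed. Far fewer genes changed there than passed in the real comparison, so the share in the real data is not known.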

Other observations

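The test of a copy-number gradient was fixed before its result was seen, and the count of genes by time of highest level was chosen afterwards. Of the 3169 genes that differed over time, 791 had their highest mean level at 0 h, 810 at 3.5 h, 507 at 10 h and 1061 at 22 h. With scaling by total counts these numbers were 430, 1537, 574 and 628. On the TMM scale the lowest mean fell at 0 h for 932 genes, at 3.5 h for 836, at 10 h for 373 and at 22 h for 1028, and with total counts these numbers were 1217, 264, 271 and 1417.

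Several runs passed through their highest level at 10 h. The run at 282570 to 286983 stood at 316 ± 1.8 CPM at 0 h, 1400 ± 109 at 3.5 h, 3530 ± 97.6 at 10 h and 254 ± 22.7 at 22 h (SD, n = 3), and the run at 2805583 to 2819068 at 1060 ± 58.7 CPM by 22 h. By contrast, the run at 3705663 to 3710384 was highest at 3.5 h. It stood at 8360 ± 2300 CPM at 0 h, 13600 ± 2970 at 3.5 h, 1880 ± 104 at 10 h and 1280 ± 108 at 22 h. FE795_06625 had its highest mean at 22 h, at 378, 360 and 1840 CPM in the replicates. The mean of the run at 2408903 to 2412640 was also highest at 22 h, but only through replicate 3. Its replicates then stood at 505, 476 and 1750 CPM, against 610 ± 37.9 CPM at 0 h.

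A hypothesis was that renewed growth raises the copy number, and so the transcripts, of genes near the replication origin, taken here as position 1 of the listed chromosome, which the files do not state to be the origin. Across 3260 locus tags the slope of log2 fold change at 3.5 h against 0 h was 0.016 per Mb of distance from position 1, with an SD of 0.04 among 1000 circular shifts of the values along the chromosome (permutation p = 0.667, adjusted p = 0.889 over 4 comparisons). No gradient was detected, and the slope lies within its spread of 0, so the data do not decide. From 3.5 to 22 h, where the hypothesis predicted a rise with distance, the slope was -0.187 per Mb with an SD of 0.15 (permutation test, adjusted p = 0.806). Genes are not independent replicates.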
